A study of Homo sapiens with 9 samples.

How the data were processed

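Polyadenylated RNA of HCT116 cells taken 48 h after siRNA transfection was sequenced in 9 libraries, 3 each of siControl, siRNF40 and siTG2. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.1, aligned with STAR 2.7.0, counted per gene with HTSeq 0.12.4 and analysed with DESeq2, and builds hg19 and hg38 are both named. The gene coordinates in the table are hg19 positions. The strand setting of the counting is not stated. The table deposited by the authors holds a signal, counts per gene divided by a DESeq2 size factor per library, for 63677 genes. Its columns marked NC were taken as siControl, since their means equal those of the deposited comparisons. Each column is a whole multiple of a single step, and all values (100%) lie within 0.001 reads of a whole read count after division by it, so whole reads were recovered. The authors also deposited 2 DESeq2 comparison tables against siControl, which hold log2 fold changes with standard errors on the log2 scale and a p-value and adjusted p-value for each gene. No p-value is given there for 28139 genes, and 29 (siRNF40) and 157 (siTG2) genes have an adjusted p of 1 beside a p under 0.05.

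The main test was limma 3.58.1 with an intensity trend on log2 of the deposited value plus 1, in R 4.3.3. All 9 libraries entered a single fit with 3 group means, without covariates. The 17663 genes with a mean value of at least 10 were tested, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were siRNF40 against siControl, siTG2 against siControl and siRNF40 against siTG2, the last being the test of the difference between the knockdown effects. Levels are means ± SD over 3 libraries, and SE is limma's moderated standard error of a log2 fold change. RNF40 and TGM2 were also compared with a two-sided exact permutation test, which cannot go below p = 0.1 for 3 against 3. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples.

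Genes were named by a rule. RNF40 and TGM2 are always named. For each knockdown, the 8 genes with the largest increase and the 8 with the largest decrease were taken among called genes with a mean of at least 100 and no overlap between knockdown and control libraries, leaving out pseudogene, antisense and clone names. The 5 highest and the 5 lowest by mean effect were taken among genes called in the same direction in both knockdowns. From each list described, up to 4 called members with the largest change and a mean of at least 50 were eligible, with up to 2 uncalled members. RNF20, RN7SL2, and the genes set side by side in the direct contrast were chosen after their values were seen.

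Gene lists, 27 in number, were written down from textbook knowledge. They cover the H2B ubiquitination machinery, transglutaminases, serotonin genes, NF-kB, p53, Wnt, ATF4 and YAP targets, ribosome biogenesis, DNA replication, mitosis, replication-dependent histones, glycolysis, hypoxia, cholesterol, fatty acid synthesis, endoplasmic reticulum chaperones, interferon-stimulated genes, mesenchymal and epithelial genes, colonic differentiation, pro-apoptotic and anti-apoptotic genes, lysosome and autophagy, fibroblast markers, leukocyte and red cell markers, and mitochondrially encoded mRNAs. All 519 entries were found in the table, 516 by symbol and 3 by gene ID. The 23 lists with at least 5 tested genes were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Unless an estimated correlation is named, a list's adjusted p is that of camera with the preset correlation. By fry, which asks whether a list's genes change in either direction and does not compare them with other genes, the highest adjusted mixed p of the 23 lists was 0.00086 in siRNF40 and 0.0039 in siTG2. The contrasts, tests, lists, naming rule and the alternatives other than those named below as added were chosen before the data were examined.

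Transcript sequences of GENCODE 29, joined by gene ID, were searched for 7-base words, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. For each of 16198 words present in at least 50 genes, the log2 fold changes of 12992 protein-coding genes (95% of 13678 tested) with a 3' UTR of at least 50 bases were regressed on presence of the word, 3' UTR length and GC content, with a Bonferroni correction over words. The siRNA sequences were not analysed here. Genomic length was compared with log2 fold change by Spearman's rho, with 1000 bootstrap draws for its interval, or 200 for partial correlations. Bootstrap intervals of correlations and of list medians resample genes and not libraries, so they leave out the spread between libraries. Because both knockdowns share the controls, 50 simulations of unchanged groups give the correlation and covariance that arise without any effect. All 9 libraries were drawn anew around the siControl means, with 1 spread per gene estimated over the 3 groups.

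The alternatives were pseudocounts of 0.1 and 10, no filter, a minimum mean of 50, quantile normalization, scaling to equal totals, edgeR 4.0.16 with TMM or with DESeq2 size factors and DESeq2 1.42.0 on the recovered reads, 6 libraries per contrast, an adjusted p under 0.01, a change of at least 1.5-fold, a replicate block, and leaving out each library in turn. Added after seeing the data were RN7SL2 as a covariate and leaving out genes that hold either strongest word. Only the 12992 searched genes could be left out in this way, and all genes not searched stayed in. On simulated data with 16946 genes, 76.1%, 85.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold were called, and 10 of 16746 unchanged genes. The changed genes numbered 67, 67 and 66 and were drawn without those of the lowest control levels. Each gene's spread followed the trend with level and not its own estimate. These shares thus need not hold in the real data, where far more genes were called. A word effect of -0.3 planted in simulated data was recovered as -0.352.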

Results

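Messenger RNA was sequenced from HCT116 cells, a human colon carcinoma line, 48 h after transfection of small interfering RNA (siRNA). The 9 libraries form 3 groups of 3 replicates, named siControl, siRNF40 and siTG2. RNF40 is a subunit of the ligase that attaches ubiquitin to histone H2B, and TG2 is transglutaminase 2, the product of TGM2, which the series links to the attachment of serotonin to histone H3. The reads assigned to genes numbered 29161285, 34143599 and 31096592 in siControl replicates 1, 2 and 3. They numbered 32574151, 35743918 and 30632268 in siRNF40 and 30577237, 33343878 and 30136581 in siTG2. Levels are given below as mean normalized read counts ± SD over 3 replicates (n = 3), and 1 read equals 0.88 to 1.1 of these units in the 9 libraries. Averaged over genes, the spread between replicates was 5.19 to 23.3 times the variance that counting error alone gives. Genes with high counts can dominate this average, so it does not tell how far depth limits genes with low counts. The first principal component held 42.8% of the variance and separated the siRNF40 libraries from the siTG2 libraries, with siControl between them. Between 25162 and 25468 genes had at least 1 read in siControl, 25296 to 25548 in siRNF40 and 27123 to 27602 in siTG2.

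Each siRNA lowered the transcript of its own target. RNF40 (ENSG00000103549), on the plus strand of chromosome 16 from 30773066 to 30787628 in build hg19, had 2780 ± 219 counts in siControl and 520 ± 20.6 in siRNF40, which is 18.7% of the control level. TGM2 (ENSG00000198959), on the minus strand of chromosome 20 from 36756863 to 36794980, had 605 ± 84.4 counts in siControl and 112 ± 48.6 in siTG2, which is 18.5%. RNF40 fell by 2.42 on the log2 scale in siRNF40 (SE 0.085, adjusted p = 5.3e-13), and TGM2 fell by 2.52 in siTG2 (SE 0.23, adjusted p = 1.1e-07). In each case all 3 knockdown libraries lay below all 3 controls, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows.

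**Figure D1:**
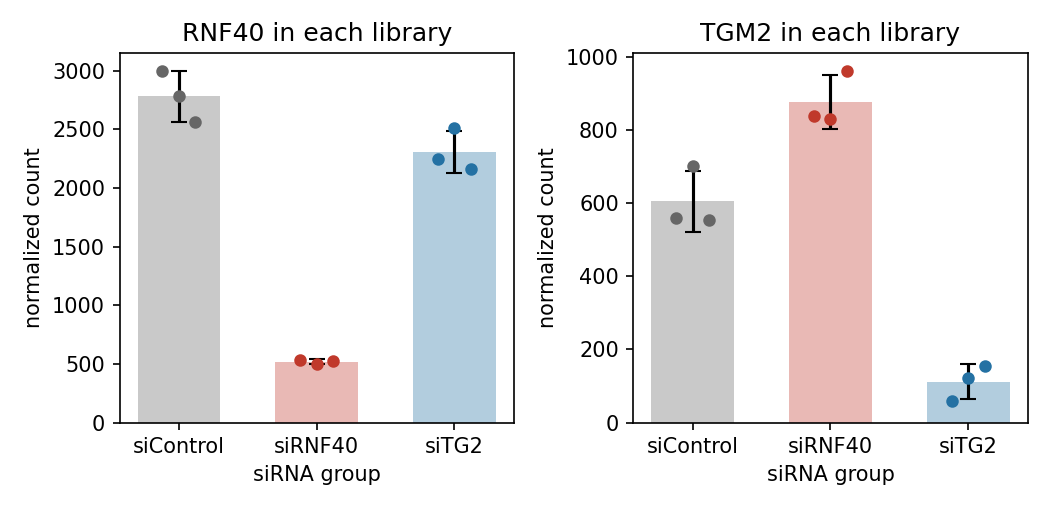
Normalized read counts of RNF40 and TGM2 in each siRNA group. Bars are means, error bars are SD and points are the 3 libraries of a group, with RNF40 between 497 and 535 in siRNF40 and TGM2 between 59.4 and 155 in siTG2.

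Each target was also measured in the other knockdown. TGM2 stood at 877 ± 74.2 counts in siRNF40, a log2 fold change of 0.54 that missed the threshold (adjusted p = 0.063). It passed without siTG2 replicate 1 (adjusted p = 0.0026) or siTG2 replicate 3 (0.031), in a fit of the 6 libraries of this comparison alone (0.00082), with a pseudocount of 10 (0.045) and with edgeR (0.024 with TMM normalization), with a range of 0.00082 to 0.98 over all alternatives. RNF40 stood at 2300 ± 180 counts in siTG2, a log2 fold change of -0.27 (adjusted p = 0.019). That call ended with a smaller change under quantile normalization (-0.15, SE 0.086 against 0.085 before, adjusted p = 0.21) and under scaling to equal totals (-0.13, SE 0.085, adjusted p = 0.26). With log2 fold changes of -0.22 to -0.27 and an SE of 0.097 to 0.1, it also ended without siControl replicate 1 (0.12), siControl replicate 2 (0.058), siTG2 replicate 1 (0.062) or siTG2 replicate 3 (0.1), with a range of 0.0077 to 0.26 over all alternatives. RNF20, the partner of RNF40 in the ligase, had 1610 counts in siControl and 1500 in siRNF40 (adjusted p = 0.32).

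The comparison of siRNF40 with siControl asks which transcripts change when the H2B ubiquitin ligase is depleted. In this polyadenylated RNA, transcripts of histones and of p53 target genes were higher in siRNF40. Those of DNA replication, mitosis and interferon-stimulated genes were lower. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 21570 ± 479 to 74310 ± 5890 counts (log2 fold change 1.78, SE 0.065, adjusted p = 5.3e-13). CTGF, a secreted matrix protein, rose from 469 ± 42 to 2756 ± 19 (2.56, SE 0.091, adjusted p = 5.3e-13). CCNE2, the cyclin E2 of entry into S phase, fell from 454 ± 4.08 to 79.2 ± 7.85 (-2.51, SE 0.14, adjusted p = 7.4e-11). Of 17663 genes tested with limma, 3825 were called higher and 4175 lower, and changes of at least 2-fold numbered 623 and 901. The siRNF40 and siControl libraries did not overlap for 53.2% of the genes, against 10% by chance. The deposited DESeq2 table calls 7613 (95.2%) of these 8000 genes in the same direction, with 3760 higher and 4055 lower in all.

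The genes named as the most changed had a mean of at least 100 counts and no overlap with the control libraries, and some genes at lower levels moved further. Of the 8 such genes with the largest increases in siRNF40, 4 were histone genes. HIST1H2BC rose from 68.6 ± 15.2 to 634 ± 45 counts, a log2 fold change of 3.21. HIST1H2AC (2.37), HIST1H2BD (2.36) and HIST1H2BJ (2.22) rose beside it. KRTAP2-3, a keratin-associated protein gene, rose by 3.13, and TNFSF18, which encodes the ligand of the GITR receptor, by 2.5. RN7SL3, a gene for the 7SL RNA of the signal recognition particle, rose by 2.19 from 56.8 ± 44.7 to 268 ± 221 counts. Another 7SL gene, RN7SL2, had 7840, 2760 and 2690 counts in siRNF40 replicates 1, 2 and 3 and 812 to 1020 in siControl. With the level of RN7SL2 as a covariate the calls numbered 1333 higher and 2098 lower, and RN7SL3 had a log2 fold change of 0.00124 (SE 0.63, against 0.47 without it; adjusted p = 1, against 9.4e-05 to 1 over all alternatives). Both genes encode 7SL RNA, so the loss of the RN7SL3 change was set in advance by this covariate. The covariate was also higher in all siRNF40 than in all siControl libraries. Fewer calls can thus come from its overlap with the group, and they do not tell whether 7SL RNA lies behind the lost ones.

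Chosen in the same way, the gene with the largest decrease was RAB27B, a small GTPase of vesicle secretion. It fell from 208 ± 7.14 to 22.9 ± 13.8 counts (log2 fold change -3.28). ESCO2, an acetyltransferase of sister chromatid cohesion, fell from 1452 ± 108 to 271 ± 33.3 (-2.42), and DTL, a substrate receptor of a ubiquitin ligase of S phase, from 2242 ± 65.4 to 424 ± 37.7 (-2.40). GGH, gamma-glutamyl hydrolase (-2.40), TRUB1, a pseudouridine synthase (-2.39), and ASF1B, a histone chaperone (-2.35), fell to a similar degree. Of the 7 lowest genes chosen in this way, without RNF40, 6 hold the 7-base word GTCTTCA in the 3' UTR, namely CCNE2, ESCO2, DTL, GGH, TRUB1 and ASF1B, against 12.9% of the 12992 protein-coding genes searched. The word also occurs in the RNF40 transcript, 2 times in the coding sequence and 1 time in the 3' UTR. Of the genes searched, 27.5% hold it somewhere in the transcript, so its presence in the coding sequence of a named gene is common. Genes with it in the 3' UTR were called lower in 53.8% of 1679 cases, and genes without it in 25.4% of 11313. GTCTTCA was picked as the word most strongly tied to lower genes in this same comparison. Its shares among the lowest and the called genes thus follow in part from that choice, and they are not matched for 3' UTR length.

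**Figure D2:**
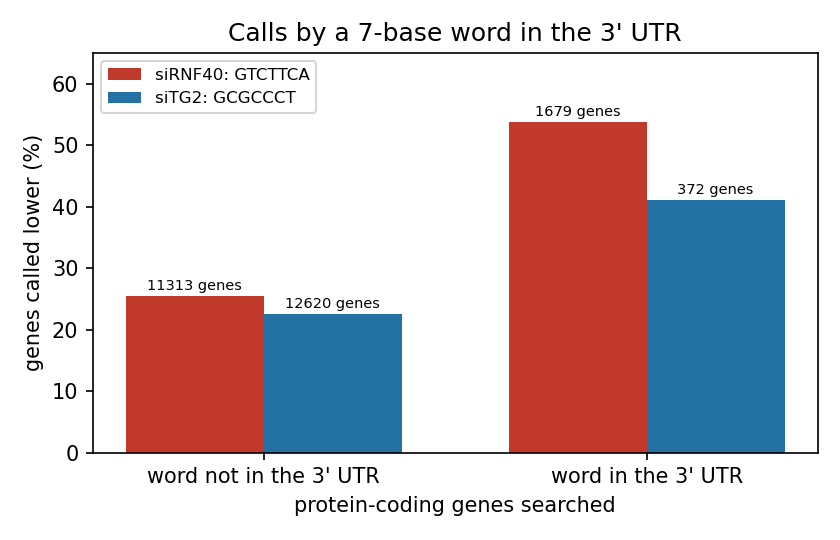
Share of protein-coding genes called lower, in percent, for genes without and with a 7-base word in the 3' UTR. Bars show GTCTTCA in siRNF40 (25.4% without, 53.8% with) and GCGCCCT in siTG2 (22.6% without, 41.1% with), with the number of genes above each bar. Each word was picked as the one most strongly tied to lower genes in the same comparison.

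Replication-dependent histone genes, whose transcripts normally end without a poly(A) tail, were higher as a group in siRNF40. The libraries were made from polyadenylated RNA, so the total level of histone transcripts was not measured in any group. Of 31 genes listed, 16 reached the level tested. Of 16 measured, 14 were called higher and none lower, with a median log2 fold change of 2.08 (camera adjusted p = 2.9e-10, and 0.0024 with an estimated correlation). HIST1H1E, a linker histone gene, rose from 17.9 ± 9.63 to 108 ± 10.3 counts. Copies within a histone family can be similar in sequence, so a single copy's value may be less certain than the list's. The p53 target genes rose in 20 of 26 cases and fell in 2 (median 0.73, adjusted p = 1.8e-09). FDXR, a mitochondrial reductase (1.54), BTG2, an antiproliferative factor with GTCTTCA in its coding sequence (1.27), and BBC3, the pro-apoptotic PUMA (1.24), rose with CDKN1A. Ribosome biogenesis genes rose in 18 of 24 cases and fell in 2 (median 0.34, adjusted p = 2.3e-05, and 0.041 with an estimated correlation). NPM1, a nucleolar chaperone, rose by 0.87. BOP1, a factor of the large ribosomal subunit, rose by 1.15 (SE 0.16; with RN7SL2 as a covariate 0.56, SE 0.25, adjusted p = 0.14, with a smaller change and a larger error; 1.8e-11 to 0.14 over all alternatives), and UTP20, which holds GTCTTCA in its coding sequence, had a log2 fold change of -0.83.

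Genes of DNA replication and S phase fell in 25 of 28 cases and rose in 1 (median -0.83, adjusted p = 2e-13, and 0.0024 with an estimated correlation). CDC6, which loads the replicative helicase, fell from 5869 ± 368 to 1702 ± 167 counts (-1.79). POLA1, a subunit of DNA polymerase alpha (-1.48), and GINS1, of the replicative helicase complex (-1.45), fell as well, and CDC6 and POLA1 hold GTCTTCA in the 3' UTR. All 25 genes of mitosis and G2/M fell (median -0.82, adjusted p = 1.1e-18, and 0.0024 with an estimated correlation). Examples were BUB1B, of the spindle checkpoint (-1.31), TPX2, a spindle factor (-1.27), the kinase CDK1 (-1.25) and TOP2A, a topoisomerase (-1.24). TPX2 holds the word in the 3' UTR, and BUB1B, CDK1 and TOP2A in the coding sequence. In the 3' UTR it occurs in 3 of the 25 mitosis genes (12%), near the 12.9% of all genes searched. Their median was -0.756, against -0.829 for mitosis genes without it. Among 27 replication genes searched, the 4 with it (14.8%) had a median of -1.64, against -0.729 without it. Without all genes that hold GTCTTCA or GCGCCCT, the strongest word in siTG2, anywhere in the transcript, the medians were -0.795 over 20 replication genes and -0.806 over 13 mitosis genes.

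Interferon-stimulated genes fell in 16 of 20 cases and none rose (median -0.86, adjusted p = 4.1e-06, and 0.0079 with an estimated correlation). IFIT1 fell from 338 ± 27.5 to 87.9 ± 30.2 counts (-1.98), IFIT3 fell by 1.41, OAS3 by 1.3 and DDX58, the RNA sensor RIG-I, by 1.03. Endoplasmic reticulum chaperones and genes of the unfolded protein response fell in 13 of 17 cases and rose in 1 (median -0.45, adjusted p = 2.5e-05, and 0.011 with an estimated correlation). Among them DNAJC3 had a log2 fold change of -1.28, DNAJB9 of -0.87 and the transcription factor XBP1 of -0.70. Adjusted over the list alone, the counts were 15 higher for histones, 18 higher and 3 lower for ribosome biogenesis, 17 lower for interferon-stimulated genes, and unchanged for the replication, mitosis, p53 and chaperone lists.

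Further lists passed the test with the preset correlation and lost the call with an estimated correlation. Genes of cholesterol synthesis and uptake rose in 8 of 22 cases and fell in 2 (median 0.23, adjusted p = 0.0097, and adjusted p = 0.17 with an estimated correlation). SREBF2, a transcription factor of the pathway, rose from 4989 ± 131 to 7638 ± 402 counts (0.61). YAP target genes rose in 8 of 16 cases and fell in 2 (median 0.31, adjusted p = 0.0086, and adjusted p = 0.17 with an estimated correlation). CTGF and CYR61 (1.61) rose, and AMOTL1 (-1.01), which holds GTCTTCA 4 times in the 3' UTR, fell. Mesenchymal and matrix genes fell in 10 of 18 cases and rose in 1 (median -0.48, adjusted p = 0.034, and adjusted p = 0.11 with an estimated correlation). LOXL2 (-1.29) and ZEB1 (-0.85), both with the word in the 3' UTR, and VIM (-0.92), without it, fell, and the ZEB1 call (SE 0.13) ended with RN7SL2 as a covariate (-0.59, SE 0.23, adjusted p = 0.079, with a range of 5.4e-09 to 0.079 over all alternatives), as the change shrank and its error grew. Glycolysis genes rose in 11 of 18 cases and fell in 4 (median 0.25, adjusted p = 0.04, and adjusted p = 0.44 with an estimated correlation). PFKP rose by 0.76, while LDHA, which makes lactate and holds the word in the 3' UTR, had a log2 fold change of -1.54. The glycolysis call also ended without siControl replicate 3 (median 0.246, adjusted p = 0.06) or siRNF40 replicate 3 (0.242, 0.064), with medians close to the full one. Without genes that hold either word anywhere in the transcript, the mesenchymal list had a median of 0.118 (adjusted p = 0.64), the YAP list 0.201 (0.64) and the cholesterol list 0.226 over 16 genes (0.087), as large as the 0.226 over all 22, so that call ended with fewer genes and not with a smaller change. Over all alternatives the adjusted p ranged from 0.00049 to 0.17 for cholesterol, 0.00035 to 0.64 for YAP targets, 0.013 to 0.64 for mesenchymal genes and 0.008 to 0.44 for glycolysis. Adjusted over the list alone, the counts were 9 higher and 2 lower for cholesterol, 8 higher and 3 lower for YAP targets, and unchanged for the mesenchymal and glycolysis lists.

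The lists closest to the design did not pass in siRNF40 in the main test. With no filter on low values, the H2B ubiquitination machinery (adjusted p = 0.038, with a range of 0.038 to 0.64 over all alternatives) and the serotonin genes (0.046, with a range of 0.046 to 0.24) did. Genes of the H2B ubiquitination machinery rose in 3 of 15 cases and fell in 6 (median -0.149, adjusted p = 0.1), with the same counts adjusted over the list alone. The list includes RNF40, the siRNA target (-2.42), so part of its test was set by the knockdown itself. Beside RNF40 itself, CDC73, of the PAF1 complex, fell by 0.96 and UBE2A, the ubiquitin-conjugating enzyme of the pathway, by 0.70, and CDC73 holds GTCTTCA in its coding sequence. Genes of serotonin synthesis, transport, breakdown and reception fell in 3 of 7 cases (median -0.55, adjusted p = 0.1), or 1 higher and 4 lower adjusted over the list alone. They were the receptors HTR1D (-1.43) and HTR7 (-0.78) and the serotonin-degrading oxidase MAOA (-0.55, SE 0.11; with RN7SL2 as a covariate -0.51, SE 0.2, adjusted p = 0.084, so mainly the precision fell; 6.4e-06 to 0.084 over all alternatives), with the word in the coding sequence of HTR7 and the 3' UTR of MAOA. Of 4 transglutaminase genes measured, 2 were called higher, or 3 adjusted over the list alone.

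Long genes were lower than short ones in siRNF40. Across 13678 protein-coding genes, Spearman's rho between genomic length and log2 fold change was -0.241 (bootstrap 95% interval -0.256 to -0.226) in siRNF40 and 0.0209 (0.00355 to 0.0381) in siTG2. The median log2 fold change in siRNF40 was 0.179 for the sixth of genes with the shortest span, up to 8.49 kb, and -0.197 for the sixth with the longest, from 111 kb. After removal of 3' UTR length, 3' UTR GC content and level of expression, the rank partial correlation was -0.129 (-0.146 to -0.112, 12992 genes) in siRNF40 and 0.0535 (0.038 to 0.0689) in siTG2, so part of the trend goes with these measures. These correlations are across genes, which are not independent replicates.

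The comparison of siTG2 with siControl asks which transcripts change when transglutaminase 2 is depleted. DNA replication and epithelial junction genes were lower in siTG2. SLC4A8, a sodium-driven bicarbonate exchanger, rose from 31 ± 8.16 to 312 ± 40.4 counts (log2 fold change 3.32, SE 0.28, adjusted p = 3.9e-08). DYNLRB1, a light chain of dynein, fell from 2174 ± 76 to 434 ± 79.3 (-2.34, SE 0.11, adjusted p = 2e-11). MGLL, monoacylglycerol lipase, fell from 1178 ± 74.4 to 244 ± 26.5 (-2.27, SE 0.11, adjusted p = 2e-11). Of the 17663 genes, 2263 were called higher and 3270 lower, and changes of at least 2-fold numbered 612 and 253. The siTG2 and siControl libraries did not overlap for 46.5% of the genes, against 10% by chance. Scaling to equal totals moved the median of all genes from -0.00685 to 0.136 on the log2 scale, and the calls then numbered 3887 higher and 1883 lower. The deposited table calls 5360 (96.9%) of these 5533 genes in the same direction, with 2316 higher and 3244 lower in all.

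Chosen in the same way, the other genes with large increases in siTG2 were diverse. CARNS1, carnosine synthase, rose by 2.28, PALM3 by 2.23, and FOLR1, a folate receptor, by 2.20. FAM46C, a poly(A) polymerase, rose by 2.08 and NOVA2, a splicing regulator of neurons, by 2.03. IFNE, which encodes interferon epsilon, rose from 59.1 ± 20.8 to 242 ± 26.1 counts (2.07), and OLFML2B rose by 1.98. The other large decreases were in FTO, an RNA demethylase (-2.24), C1orf116 (-2.05), TMEM158 (-2.05), CHCHD10, a mitochondrial protein (-2.03), and ABHD2, a serine hydrolase (-2.01). Of the 7 lowest genes chosen in this way, without TGM2, DYNLRB1, MGLL and ABHD2 hold the 7-base word GCGCCCT in the 3' UTR, against 2.86% of the genes searched, and CHCHD10 holds it in the coding sequence, as does CARNS1, which rose. The word also occurs 1 time in the coding sequence of TGM2, and somewhere in the transcript of 16% of the genes searched. Genes with it in the 3' UTR were called lower in 41.1% of 372 cases, and genes without it in 22.6% of 12620. GCGCCCT was likewise picked from these same fold changes, so its shares follow in part from that choice.

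Genes of DNA replication and S phase fell in 22 of 28 cases and rose in 1 (median -0.46, adjusted p = 9.8e-10, and 0.007 with an estimated correlation). GINS2, of the replicative helicase complex, fell from 531 ± 10.3 to 205 ± 35.4 counts (-1.38), the licensing factor CDT1 fell by 0.91, and the helicase subunits MCM3 and MCM2 fell by 0.91 and 0.90. MCM2 holds GCGCCCT in its coding sequence. Epithelial junction and keratin genes fell in 11 of 20 cases and rose in 1 (median -0.32, adjusted p = 0.00033, and 0.049 with an estimated correlation), and the call ended under quantile normalization (median -0.194, bootstrap 95% interval -0.461 to -0.014, against -0.422 to -0.19 before; adjusted p = 0.058, with a range of 7.1e-08 to 0.058 over all alternatives). CLDN7, a tight junction protein, fell from 7297 ± 267 to 3862 ± 458 counts (-0.92), and JUP, plakoglobin (-0.83), with GCGCCCT in its coding sequence, and ESRP1, an epithelial splicing factor (-0.72), fell as well. CLDN3, which also holds GCGCCCT in its coding sequence, rose by 0.68. Genes of mitosis and G2/M fell in 15 of 25 cases and rose in 1 (median -0.29, adjusted p = 6.9e-05). That call ended with an estimated correlation (adjusted p = 0.058 with an estimated correlation) and under quantile normalization (median -0.105, bootstrap 95% interval -0.232 to 0.0124, against -0.354 to -0.139 before; adjusted p = 0.084), with a range of 1.7e-09 to 0.084 over all alternatives. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell by 1.32 and cyclin CCNB2 by 0.61.

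Histone genes rose in 7 of 16 cases and none fell (median 0.44, adjusted p = 0.0033, and adjusted p = 0.058 with an estimated correlation), and the call ended under quantile normalization (0.066, with a range of 0.0015 to 0.066 over all alternatives). The median there was 0.481 (bootstrap 95% interval -0.0833 to 0.711), against 0.182 to 0.906 before, so the median was no smaller while the interval reached below 0. HIST1H1E rose by 1.44 and HIST1H2BC by 1.1, in libraries where RN7SL2 had 820, 2320 and 1510 counts. Ribosome biogenesis genes fell in 10 of 24 cases and none rose (median -0.18, adjusted p = 0.011, and adjusted p = 0.19 with an estimated correlation). Among them NOP16 fell by 0.56 and NOP58 by 0.40. The ribosome biogenesis call also ended without siTG2 replicate 3 (median -0.145, adjusted p = 0.052), with a minimum mean of 50 (-0.178, 0.065), under quantile normalization (-0.0329, 0.51) and under equal totals (-0.0345, 0.2), with a range of 5e-05 to 0.51 over all alternatives. Adjusted over the list alone, the counts were 12 lower for the epithelial list, 17 lower for mitosis, 11 lower for ribosome biogenesis, and unchanged for replication and histones.

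The other lists did not pass in siTG2 in the main test, and some held members that moved far. Wnt target genes rose in 7 of 15 cases and fell in 4 (median 0.49, adjusted p = 0.29). NOTUM, NKD1 and AXIN2, which are feedback inhibitors of the Wnt pathway, rose by 1.47, 1.36 and 1.3, NOTUM with GCGCCCT in its coding sequence, and the Wnt antagonist DKK1 fell by 1.36. Without genes that hold either word anywhere in the transcript, NOTUM and DKK1 among them, the Wnt list passed (median 0.79, adjusted p = 0.0021, with a range of 0.0021 to 0.46 over all alternatives). DKK1 was left out for GTCTTCA in its coding sequence, a word that did not mark lower genes in siTG2 (t = 0.26). Of the genes searched, 27.5% hold GTCTTCA anywhere in the transcript and 16% hold GCGCCCT. Passes in siTG2 without carriers of either word, here and below, thus also drop genes for the word of the other knockdown. Interferon-stimulated genes rose in 4 of 20 cases and none fell (median 0.22, adjusted p = 0.095), or adjusted p = 0.033 without the genes that hold either word (0.033 to 0.19 over all alternatives). BST2 rose by 1.21 and IFI6 by 1.00. The p53 target genes rose in 5 of 26 cases and fell in 7 (median 0.02, adjusted p = 0.82), or 8 and 7 adjusted over the list alone, and CDKN1A had 21300 ± 1190 counts. Mesenchymal and matrix genes rose in 6 of 18 cases and fell in 2 (median 0.00433, adjusted p = 0.63), with FN1, fibronectin, at 1.24 and PLAUR, the urokinase receptor, which holds GCGCCCT in its coding sequence, at -1.11. Without the genes that hold either word anywhere, the mesenchymal list passed (median 0.275, adjusted p = 0.013, with a range of 0.013 to 0.8 over all alternatives). Endoplasmic reticulum chaperones fell in 7 of 17 cases and rose in 1 (median -0.17, adjusted p = 0.095), but passed with no filter on low values (0.0046) and without the genes that hold either word anywhere (0.019), with a range of 0.0046 to 0.83 over all alternatives. Among them HSPA5, the chaperone BiP, fell from 179100 ± 3840 to 115600 ± 4650 counts. Adjusted over the list alone, the counts were 1 higher and 8 lower for the chaperones, 6 and 3 for the mesenchymal list, and unchanged for the Wnt and interferon lists. Of the serotonin genes 1 rose and 2 fell among 7 (adjusted p = 0.63), with HTR7 at -0.54, and of the H2B machinery 1 rose and 1 fell among 15 (adjusted p = 0.82), or 0 and 0 adjusted over the list alone. Of 4 transglutaminase genes, TGM2 alone was called.

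**Figure D3:**
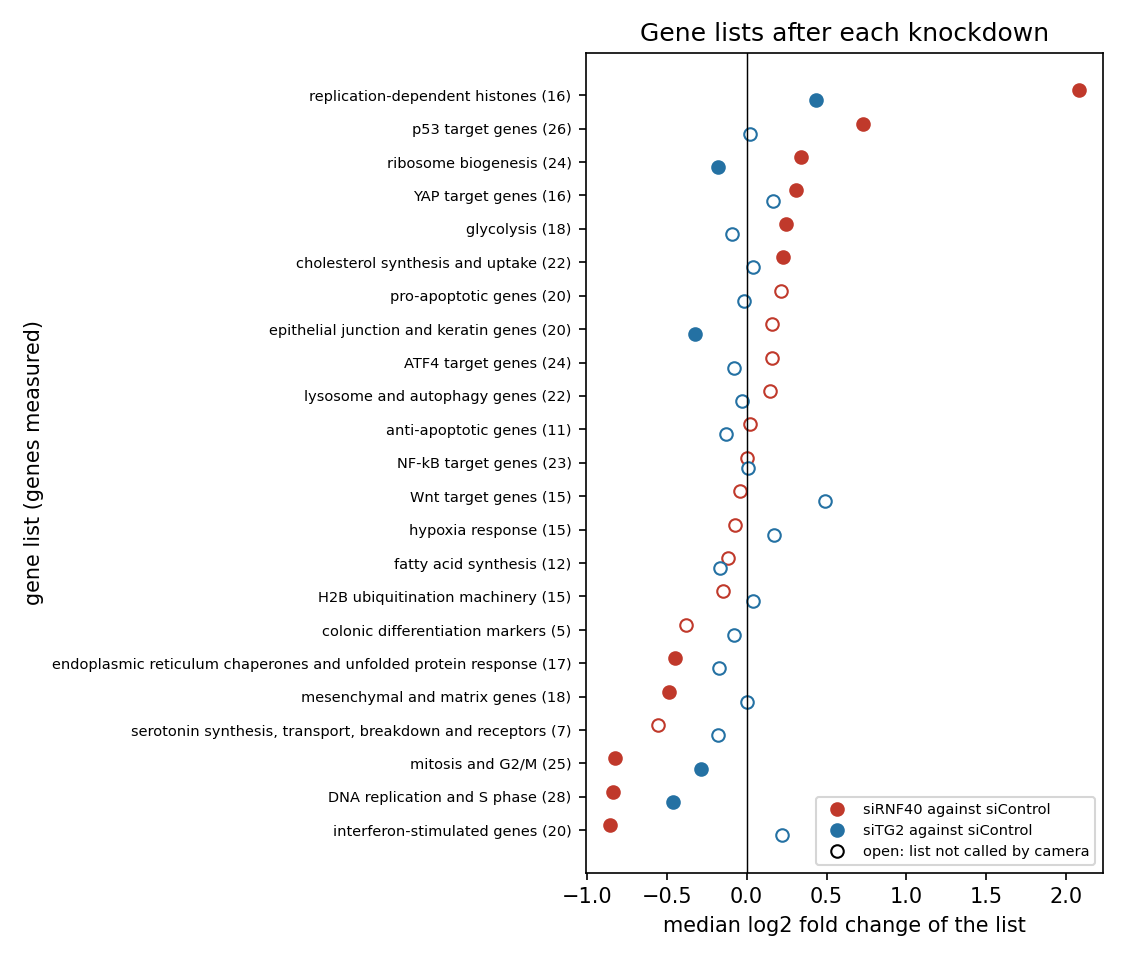
Median log2 fold change of 23 gene lists in siRNF40 (red) and siTG2 (blue) against siControl, with the number of genes measured in parentheses. Filled points passed camera with the preset correlation, 11 in siRNF40 and 5 in siTG2, and open points did not.

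The direct contrast of siRNF40 with siTG2 tests whether the knockdown effects differ, which matters because both were measured against the same controls. In the polyadenylated RNA, histone, p53 target and ribosome biogenesis transcripts were higher in siRNF40 than in siTG2, and mitosis and interferon-stimulated transcripts were lower. NOTUM had 99.4 ± 27.5 counts in siRNF40 and 790 ± 78.7 in siTG2, and MYC, a driver of growth, had 9632 ± 433 and 3788 ± 197. C1orf116, which holds GTCTTCA in the 3' UTR, had 2353 ± 93.3 counts in siRNF40 and 256 ± 49.3 in siTG2. IFNE had 16.7 ± 7.52 and 242 ± 26.1. In all, 4704 genes were higher in siRNF40 and 4706 lower. Scaling to equal totals moved the median of all genes from -0.0144 to -0.19 and gave 3270 higher and 6325 lower.

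The list tests of the difference followed those contrasts. Histone genes were higher in siRNF40 in 11 of 16 cases and none was lower (median difference 1.33, adjusted p = 3.9e-06), or 12 adjusted over the list alone. The p53 targets were higher in 20 of 26 cases and lower in 5 (median 0.70, adjusted p = 2.4e-06), and ribosome biogenesis genes in 18 and 2 of 24 (median 0.60, adjusted p = 2.7e-06). Mitosis genes were lower in 23 of 25 cases and higher in 1 (median -0.66, adjusted p = 1.5e-09), and interferon-stimulated genes were lower in 17 of 20 with none higher (median -1.16, adjusted p = 2.4e-06). Epithelial junction and keratin genes were higher in 13 of 20 cases and lower in 2 (median 0.51, adjusted p = 0.00056). These 6 calls held with an estimated correlation, and the counts of the last 5 lists were the same adjusted over the list alone. The calls of DNA replication (median -0.28, adjusted p = 0.058 with an estimated correlation), endoplasmic reticulum chaperones (-0.24, adjusted p = 0.1 with an estimated correlation) and YAP targets (0.26, adjusted p = 0.23 with an estimated correlation) did not. The replication call also ended without genes that hold either word in the 3' UTR (median -0.132 over 24 genes, adjusted p = 0.087, with a range of 0.0012 to 0.087 over all alternatives). The YAP call also ended without siTG2 replicate 2 (median 0.253, adjusted p = 0.052, with a range of 0.00076 to 0.23 over all alternatives).

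Some genes were called in the same direction in both knockdowns. Called higher in both were HIST1H2BC, CTGF, HIST1H2BJ, ZNF506 (1.85 in siRNF40 and 1.53 in siTG2) and PKD1L2 (1.94 and 1.24). The siTG2 call of HIST1H2BJ (0.87, SE 0.24) ended with a smaller change under quantile normalization (0.65, SE 0.24, adjusted p = 0.05, with a range of 0.0034 to 0.05 over all alternatives). Called lower in both were GGH (-2.40 and -1.14), DTL (-2.40 and -0.94), ESCO2 (-2.42 and -0.71), ABHD2 (-0.99 and -2.01) and E2F7, a repressor of the cell cycle (-1.86 and -1.18). GGH, DTL, ESCO2 and ABHD2 hold GTCTTCA in the 3' UTR, ABHD2 also holds GCGCCCT there, and E2F7 holds neither. ZNF506, which rose, holds GTCTTCA in its coding sequence. In number, 631 genes were higher in both, where independent lists give 490, and 1152 were lower in both, where independent lists give 773. Opposite calls numbered 1388, of which 909 were higher in siRNF40 and lower in siTG2 (708 for independent lists) and 479 the reverse (535). How many same-direction calls the shared controls add was not estimated. Of the 4829 genes called in siRNF40 and not in siTG2, 3984 also differed in the direct contrast, as did 1901 of the 2362 called in siTG2 and not in siRNF40. Across genes, which are not independent replicates, the effects correlated with Pearson's r = 0.161, against 0.485 to 0.525 in simulated unchanged groups with shared controls. Real effects change r as well, so this difference does not tell whether the knockdowns are alike. The covariance of the effects, 0.0604, exceeded the simulated mean of 0.0438 by 0.0166. That simulated mean rests on a spread pooled over groups. Control pairs differed by 5.19 to 8.78 times counting variance, siRNF40 pairs by 15.1 to 23.3 and siTG2 pairs by 7.41 to 17.9, so it may not match the noise of the controls.

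**Figure D4:**
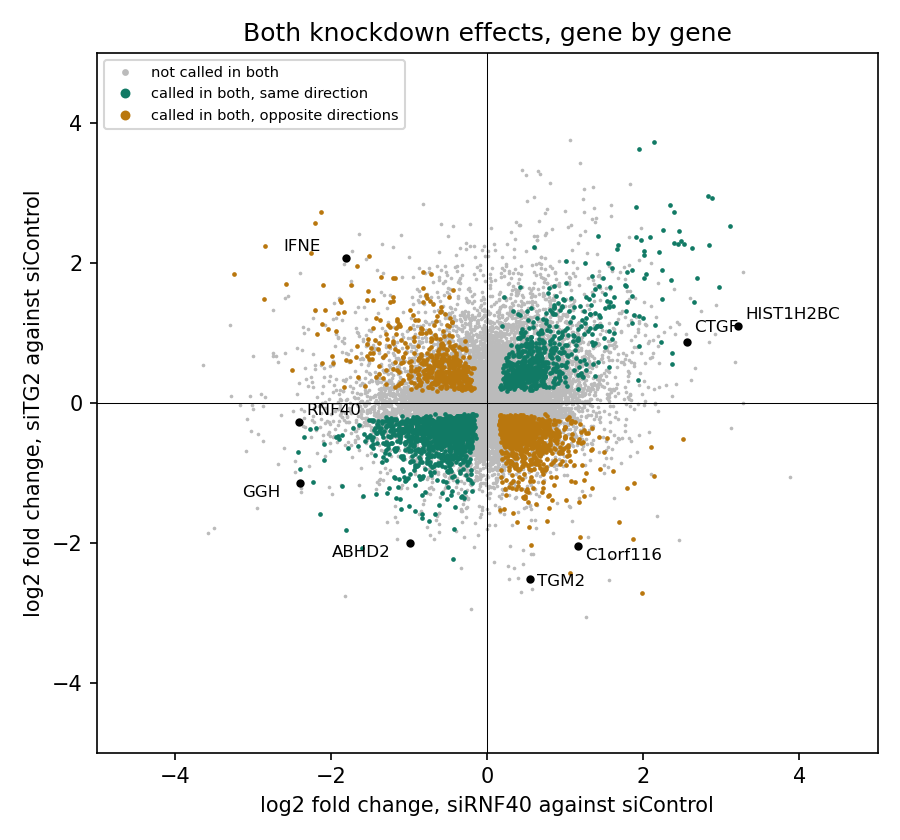
Log2 fold change of each tested gene in siRNF40 (horizontal) and siTG2 (vertical) against siControl. Green points are the 1783 genes called in both in the same direction, orange points the 1388 called in opposite directions, grey points all others, and black labelled points are RNF40, TGM2 and other named genes.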

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

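The tests of S phase share, of 7SL RNA, of words within the replication and mitosis lists, and of other measures behind the length trend were chosen after the results were seen; those of untailed RNAs, words in all genes, gene length and sample splits were chosen before. For 6 gene lists the direct contrast showed that the effects of the knockdowns differ. Replication-dependent histones were higher in siRNF40 than in siTG2 by a median of 1.33 on the log2 scale (limma camera adjusted p = 3.9e-06, and 0.011 with an estimated correlation). Interferon-stimulated genes had a median difference of -1.16 (adjusted p = 2.4e-06, and 0.011 with an estimated correlation). For p53 target genes it was 0.702 (adjusted p = 2.4e-06, and 0.011 with an estimated correlation). For mitosis and G2/M genes it was -0.658 (adjusted p = 1.5e-09, and 0.011 with an estimated correlation). For ribosome biogenesis genes it was 0.596 (adjusted p = 2.7e-06, and 0.03 with an estimated correlation). For epithelial junction and keratin genes it was 0.507 (adjusted p = 0.00056, and 0.028 with an estimated correlation).

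Replication-dependent histone genes were higher in siRNF40 by a median of 2.08 over 16 genes. A larger share of cells in S phase would raise DNA replication genes too, but their median was -0.834 (bootstrap 95% interval -1.1 to -0.629, 28 genes). Levels of these genes are no direct measure of S phase share. The 4 genes with GTCTTCA in the 3' UTR fell further than those without it (median -1.64 against -0.729). The list may thus move for other reasons, and this test cannot decide. With RN7SL2 as a covariate the histone median was 2.05 (1.37 to 2.53). That interval resamples genes and leaves out the error of the covariate, which was higher in all siRNF40 than in all siControl libraries. In siRNF40 replicates 1, 2 and 3, log2 RN7SL2 was 12.94, 11.43 and 11.39 and the mean log2 histone level 7.944, 7.955 and 7.914. In siTG2 these were 9.681, 11.18 and 10.56 beside 6.361, 6.657 and 6.532, a small rise. Together the values argue against unequal carryover of 7SL RNA as the whole cause. Carryover of other RNA without a poly(A) tail stays open, since 15 such small RNAs had a median of -0.102 with an interval of -0.381 to 1.4 and a median level of only 20.1 counts. A candidate explanation is that loss of RNF40 leaves more histone transcripts with poly(A) tails, which was not tested.

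Genes with the word GTCTTCA in the 3' UTR were lower in siRNF40 (t = -20.1, effect -0.327 on the log2 scale, 1679 genes) and not in siTG2 (t = 0.26), and genes with GCGCCCT were lower in siTG2 (t = -9.44, effect -0.264, 372 genes). Each word occurs in the transcript of the targeted gene, as do 24.9% and 24.1% of all words in RNF40 and TGM2, and this is consistent with siRNA seeds that pair with other transcripts. Compared with genes matched in 3' UTR length and GC content, 357 more carriers were called lower in siRNF40, which is 9.45% of the genes called lower among those searched, and 69.8 more in siTG2, or 2.33%; carriers in the coding sequence alone, not in those counts, were lower too (effect -0.259, 1788 genes, and -0.134, 1176 genes), and 21 and 11 words in all passed the Bonferroni threshold in the lower direction, against 4 and 0 in the higher direction. Without genes that hold either word anywhere in the transcript, the medians in siRNF40 were -0.795 (-0.981 to -0.564, 20 genes) for DNA replication and -0.806 (-0.834 to -0.719, 13 genes) for mitosis, which argues against exact matches to these words as the whole cause of their fall. Of the lists, 27 of 28 replication genes and all 25 mitosis genes had been searched. Genes with the overlapping words TCTTCAA or AGTCTTC, which also marked lower genes (t = -11.3 and -10.2), were not left out. Direct pairing through such words therefore stays open. Indirect effects of such pairing, and loss of RNF40 or TG2 itself, stay open as causes of the lower transcripts and were not tested.

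Long genes were lower than short ones in siRNF40, with a Spearman's rho of -0.241 over 13678 genes and 0.0209 in siTG2. After removal of 3' UTR length, 3' UTR GC content and level of expression, the rank partial correlation was -0.129 (-0.146 to -0.112, 12992 genes), which argues against these as the whole cause. Over the 11313 genes without GTCTTCA in the 3' UTR it was -0.134 (-0.153 to -0.118), and over the 9417 genes without it anywhere in the transcript -0.121 (-0.14 to -0.099), which argues against carriers of the word as the whole cause. The negative rho, stronger than in siTG2, is consistent with lower output of long genes after depletion of RNF40, a biological explanation that stays a hypothesis, and measures correlated with length that were not examined stay open.

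The 6 libraries of each contrast make 10 splits into groups of 3, too few for a share under 0.05. Only 1 split, the real one, gave as many calls in each contrast, with 8000 calls in siRNF40 against siControl, 5533 in siTG2 against siControl and 9410 in siRNF40 against siTG2, and the highest of the other splits gave 0 in each. The other splits mix libraries of both groups, which widens the spread within each new group. Few calls there were thus nearly fixed in advance, and no conclusion is drawn from the 0.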

How the results depend on the processing

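The RN7SL2 covariate and the removal of genes with either word were chosen after the data were seen; the other alternatives were planned. Of 248 recomputed values of the 10 main results, 211 stayed within 1.5 times the main count (or, for the correlation, within 0.0318, the SD over left-out libraries) and 37 did not. The correlation of both effects, 0.161, was 0.118 with pseudocount 10, 0.314 with no filter, 0.0666 with a minimum mean of 50, 0.127 with quantile normalization and 0.279 with the RN7SL2 covariate. Genes lower in both numbered 746 with quantile normalization. With equal totals, siTG2 gave 3887 higher and 1883 lower, and the overlaps were 978 higher and 679 lower in both. At an adjusted p under 0.01, siTG2 gave 1337 higher, with 281 higher in both, 684 lower in both and 752 opposite. With a change of at least 1.5-fold, the counts higher and lower were 1724 and 2156 in siRNF40, 1233 and 941 in siTG2, 2466 and 2854 in the direct contrast, with 232 and 161 in both and 257 opposite, as fewer genes can pass. The RN7SL2 covariate gave 1333 and 2098 in siRNF40, 204 higher and 670 lower in both and 543 opposite. It was higher in all siRNF40 than in all siControl libraries, so fewer calls can come from its overlap with the group. Without the searched genes that hold either word anywhere, 12615 genes were left to test, genes never searched for the words among them. They gave 2121 lower in siRNF40, 1448 higher and 1948 lower in siTG2, 2611 lower in the direct contrast, 557 lower in both and 834 opposite. With each library left out in turn, siRNF40 gave 3332 to 3892 higher and 3632 to 4181 lower, siTG2 1743 to 2555 and 2653 to 3595, the direct contrast 4270 to 4658 and 4126 to 4687, and the overlaps 469 to 623 higher in both, 843 to 1244 lower in both and 960 to 1457 opposite, with a correlation of 0.132 to 0.226. Of 9 libraries 3 correlated best with one of their own number, and the replicate block gave 3693 and 4042, 2122 and 3042, and 4594 and 4609, and edgeR with TMM 3718 and 4208, 2473 and 2982, and 4457 and 4973. Of 1434 list values, 31 lost the call and 33 gained it. Of 69 list results, 39 kept their side of the threshold in all alternatives, and of 217 named gene results 183 did. Of 4557 gene values, 93 lost the call, 7 gained it and 1 changed sign and was no longer called. That was ENY2 in siRNF40, at -0.112 with the RN7SL2 covariate (limma adjusted p = 0.68) against 0.42. Apart from the stricter fold and the removal of genes, the cause was not tested. Averaged over genes, replicates differed by more than counting error, and what more depth would do for genes with low counts was not tested.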

Other observations

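The levels of low-count genes and of nuclear copies of mitochondrial sequence were examined after the data were seen; the gene lists were planned. In siRNF40, several lists held members that moved in opposite directions and did not pass camera. The ATF4 target list rose in 11 of 24 cases and fell in 6 (median 0.16, adjusted p = 0.1), or 12 and 6 adjusted over the list alone. It passed with no filter on low values (0.039), without genes that hold either word in the 3' UTR (0.031) and without genes that hold either anywhere (median 0.323, adjusted p = 0.00058), with a range of 0.00058 to 0.57 over all alternatives. ATF3, a stress transcription factor, rose from 4925 ± 135 to 10230 ± 207 counts, while SLC7A5, an amino acid transporter with GTCTTCA in the 3' UTR, fell from 51670 ± 827 to 26260 ± 1070. In fatty acid synthesis, 2 of 12 genes rose and 5 fell (median -0.116, adjusted p = 0.23), with FASN at 0.95 and ACSL3 at -1.52, both with the word in the coding sequence. NF-kB targets rose in 6 of 23 cases and fell in 6 (adjusted p = 0.85), with TRAF1 at -1.12. Wnt targets rose in 5 of 15 cases and fell in 3 (adjusted p = 0.85), with MYC at 0.73 and NOTUM, with GTCTTCA in the coding sequence, at -1.54. Hypoxia genes rose in 3 of 15 cases and fell in 4 (adjusted p = 0.67), with MXI1 at 0.51. Epithelial genes rose in 10 of 20 cases and fell in 5 (median 0.16, adjusted p = 0.1), with KRT8, a keratin, at 0.88 and ESRP1, with GTCTTCA in the coding sequence, at -0.65. The epithelial list passed with no filter (0.032) and without genes that hold either word anywhere (0.019), and the pro-apoptotic list with no filter (0.031), with ranges of 0.019 to 0.18 and 0.031 to 0.39 over all alternatives. Of 5 colonic differentiation markers 2 fell (adjusted p = 0.59), CA2, a carbonic anhydrase, at -0.56 among them. Pro-apoptotic genes rose in 8 of 20 cases and fell in 4 (adjusted p = 0.1), with BAX at 0.87. Anti-apoptotic genes rose in 4 of 11 cases and fell in 4 (adjusted p = 0.91), with BCL2L2 at 0.625. Lysosome and autophagy genes rose in 8 of 22 cases and fell in 4 (adjusted p = 0.22), with TFEB, their transcription factor, at 1.04. For the NF-kB and anti-apoptotic lists the median was above 0 and the mean below 0, and for the Wnt list both were below 0 while camera pointed up. Adjusted over the list alone, the counts were 2 higher and 6 lower for fatty acid synthesis, 9 and 4 for lysosome and autophagy, and the same as above for the others.

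In siTG2 single members of the lists that did not pass moved far. YAP targets rose in 4 of 16 cases and fell in 4 (adjusted p = 0.7), with F3, tissue factor, falling from 2795 ± 131 to 1010 ± 44.8 counts (-1.47). Lysosome and autophagy genes rose in 5 of 22 cases and fell in 4 (adjusted p = 0.84), with SQSTM1, an autophagy receptor that holds GCGCCCT in the coding sequence, rising from 21120 ± 184 to 44560 ± 2700 counts (1.08). NF-kB targets rose in 4 of 23 cases and fell in 7 (adjusted p = 0.89), with the adhesion receptor ICAM1 at 1.15. Glycolysis genes rose in 4 of 18 cases and fell in 7 (adjusted p = 0.82), with the glucose transporter SLC2A1 at 0.65 and ENO1 at -0.55. Hypoxia genes rose in 5 of 15 cases and fell in 1 (adjusted p = 0.14), with EGLN3 at 0.89. Cholesterol genes rose in 5 of 22 cases and fell in 2 (adjusted p = 0.35), with INSIG1 at 0.80. Fatty acid genes rose in 2 of 12 cases and fell in 6 (adjusted p = 0.095), with SCD, a desaturase, at -0.67. ATF4 targets rose in 2 of 24 cases and fell in 7 (adjusted p = 0.35), with STC2 at -0.52. Pro-apoptotic genes rose in 4 of 20 cases and fell in 6 (adjusted p = 0.82), with BMF at 1.64. Anti-apoptotic genes fell in 4 of 11 cases and none rose (adjusted p = 0.12), with BCL2L1 at -0.54 and MCL1 at -0.39. Of 5 colonic markers 1 rose and 1 fell (adjusted p = 0.82), with KLF4, which holds GCGCCCT in the coding sequence, at -0.69. Fatty acid and anti-apoptotic genes passed with no filter (0.0048 and 0.022) and without genes that hold either word in the 3' UTR (0.049 and 0.046), anti-apoptotic genes also without those that hold either anywhere (0.011), and hypoxia genes with quantile normalization (0.031). Over all alternatives the adjusted p ranged from 0.0048 to 0.83, 0.011 to 0.51 and 0.031 to 0.29 for these lists. Adjusted over the list alone, the counts higher and lower were 6 and 4 for YAP targets, 5 and 8 for NF-kB targets, 5 and 8 for glycolysis, 6 and 2 for hypoxia, 0 and 5 for anti-apoptotic genes, 1 and 2 for colonic markers, and the same as above for the others. Median and mean differed in sign for the YAP, colonic and pro-apoptotic lists, and camera pointed up for the lysosome list, whose median and mean were below 0.

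Markers of other cell types were mostly below the level tested. Of 12 fibroblast markers 4 were measured, of which COL1A1, TAGLN and ACTA2 were called higher in siRNF40, and ACTA2 (0.64, SE 0.22) lost the call without siControl replicate 1 (0.47, SE 0.23, adjusted p = 0.12), siRNF40 replicate 1 (0.63, SE 0.25, adjusted p = 0.053) or siRNF40 replicate 3 (0.53, SE 0.25, adjusted p = 0.093), with a range of 0.014 to 0.24 over all alternatives. With RN7SL2 as a covariate TAGLN, which holds GTCTTCA in the coding sequence, lost it too (0.63, SE 0.31, against 0.71, SE 0.17; adjusted p = 0.18, with a range of 0.00023 to 0.18), mainly through lower precision. COL1A1 had 889 ± 87.2 counts in siControl and 1463 ± 175 in siRNF40. In siTG2, TAGLN was called (0.46, SE 0.17), a call that ended at 0.36 to 0.51 with an SE of 0.19 without siControl replicate 1 (adjusted p = 0.057), 2 (0.12) or 3 (0.096) and without siTG2 replicate 1 (0.18) or 2 (0.11), with a range of 0.01 to 0.2 over all alternatives. Of 12 leukocyte and red cell markers only CSF1R was measured, at 9.71 ± 4.01 counts in siControl, and it was not called. The 13 mitochondrially encoded mRNAs were at 0 in all 9 libraries, while 197 nuclear copies of mitochondrial sequence held 4.73% to 5.52% of the reads of a library. Both values may come from the alignment, since it is not stated whether the mitochondrial chromosome was part of the index.

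The siTG2 libraries held reads in more genes of low level. Of 17875 genes below the level tested, 9473 to 9949 had at least 1 read in siTG2, 7541 to 7815 in siControl and 7673 to 7913 in siRNF40. In units of 1000 counts, the summed values of these genes were 42.9 to 46.3 in siTG2, 31.3 to 32.3 in siControl and 32.9 to 36 in siRNF40.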
